A study of Mus musculus with 2 samples.

How the data were processed

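The series holds 2 two-colour Agilent mouse whole-genome arrays. Each array carried the same 2 RNA pools, per the labels: smooth muscle from the aortic arch segment and from the central thoracic aorta of 6 apoE-/- mice aged 16 weeks (4 months), with 12 µl of extract per mouse pooled and RNA integrity numbers between 7.5 and 7.7. Per the labels' protocols, 5 µg of RNA made by in vitro transcription was labelled with Cy3 or Cy5 from random nonamers. On array 1 the thoracic pool was in red (Cy5) and the arch pool in green (Cy3), and on array 2 the dyes were exchanged, which gives the direction of every ratio. As both arrays hold the same 2 pools they were treated as 1 replicate. There is 1 pool per segment, so no test, standard error over mice or p-value could be computed, and differences were called by size.

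The deposited scanner tables give intensity values per spot: the mean signal of red and green and the median of the local background, with no normalization. They were made with Agilent Feature Extraction 8.1.1.1, per the file headers, while the submitters' processing notes name version 9.1.1.1. The deposited processed signals are also intensity values, with a spatial background surface and an offset subtracted and then scaled linearly and by lowess between dyes, per the file headers. The deposited log ratio is the log10 of red over green processed signal. It is set to 0 at 3202 gene spots of array 1 and 2892 of array 2. Feature Extraction's deposited p-value per spot covers scanner and spot error on 1 array only and was used in 1 alternative. The deposited table of the whole series holds log10 ratios. Its columns had medians of 0.00 and correlations of 1.00 with the scanner's log ratio averaged per probe and turned to arch over thoracic (35 of 41174 probes differed by over 0.001 on array 1 and 38 on array 2), so scale and direction are settled and it nearly repeats the scanner's log ratio. The genome build behind the probe annotation is not given in the sources used here, and no coordinates are printed.

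The main values were computed with limma 3.58.1 in R 4.3.3 from the mean signals. Background was corrected by normexp with an offset of 50 against the local background. Each array was normalized by loess, with control spots at weight 0. Control spots and spots marked as non-uniform or population outliers (8 on array 1, 5 on array 2) were then left out, spots of 1 probe were averaged, array 1 was turned to arch over thoracic and both arrays were averaged. Local backgrounds (medians of 55 to 66) lay under the negative control spots (means of 77.0 to 97.1), so unspecific signal and the offset pull the ratios of dim probes towards 0. Of 41161 probes, 32176 were well above background in at least 1 RNA on both arrays by Feature Extraction's flags. The brightest such probe stood for its gene, leaving 22811 genes. Of the genes that passed, 44 had more than 1 such probe, and in 30 of these a further probe was under 1.5-fold or pointed the other way (the report gives that probe's value for the genes it names). Of the passing genes, 0 had an RNA that was below that limit on both arrays, and 0 sat on a saturated probe. For named genes with such an RNA that did not pass, the fold is given as a bound, against the higher of the lowest signal well above background in that channel and the probe's own signal. Among all genes compared, 58 had a saturated probe.

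Gene names came from the files' accessions through a RefSeq table of assembly GRCm38.p6, used for names alone: 21706 of 41534 gene spots matched by accession, 5476 already carried a current symbol, 4672 matched a unique synonym and 9680 kept the file's name. A gene passed when its mean log2 ratio was at least 1 in size and at least 0.585 (1.5-fold) in the same direction on each array. The mirrored rule applied the same limits to red over green without turning. The comparison, the gene lists, the alternatives below and the rule for named genes were fixed before the data were examined. The genes named in the report are the 12 largest per direction with a gene symbol (no clone, predicted or accession-type name), up to 4 members of each of 39 gene lists (passing genes first, by size), Apoe and the sex-linked genes. A few genes that this rule selects are not reported here.  For each list with at least 5 genes compared, the median was placed among 10000 lists of the same size drawn at random, with replacement, from all genes compared in the same 20 bins of brightness. A list was said to stand apart at percentile 2.5 or lower or 97.5 or higher, which describes these pools and is no p-value. The marker lists of other cell types are macrophage, lymphocyte and thymus, brown fat, adipocyte, heart muscle, skeletal muscle, endothelium, adventitial fibroblast, Schwann cell and neuron, melanocyte, mesothelium and epithelium, thyroid and parathyroid, erythroid, and cartilage and bone.

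The steps were tested on simulated arrays with the brightness, background and noise of the real ones, a dye trend and 200 changed genes, in the comparison of arch with thoracic (22014 genes compared). Of the changed genes that could be compared, 0 of 48 changed 1.5-fold, 1 of 49 changed 2-fold, 25 of 50 changed 3-fold and 29 of 50 changed 4-fold were called, none the wrong way, and 0 unchanged genes were called. Among the 12 brightest genes changed 2-fold, 1 was called. The rule therefore misses most true 2-fold differences, and many larger ones of dim genes. Median recovered folds were 1.25, 1.52, 1.97 and 2.50. Among the brightest genes they were 1.46, 1.88, 2.72 and 3.65. Of 200 simulated lists of unchanged genes 10 stood apart. Probes spotted 10 times (40 probes) had a median SD between spots of 0.04 log2 on either array.

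The alternatives were no background subtraction, normexp without an offset, the deposited log ratio, the series table, median centring in place of loess, scaling between arrays, stricter and no filters on dim probes, the median over a gene's probes, outlier spots kept, saturated probes left out, each array alone, limits of 1.5-fold and 3-fold, the scanner's p-value as a further limit, and random lists not matched on brightness. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.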

Results

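RNA from the aortic wall of apoE-/- mice, which lack apolipoprotein E and develop atherosclerosis, was compared between an atherosclerosis-prone and an atherosclerosis-resistant stretch of the same vessel. The prone segment, called arch below, held the aortic root, the arch and the first 2 mm of the thoracic aorta. The resistant segment, called thoracic below, was the next 6 mm of the thoracic aorta. The vessels were perfused with a detergent meant to remove the endothelium, as smooth muscle was the cell type the study was after. RNA of 6 mice (3 males and 3 females, 16 weeks old) was pooled per segment, and the 2 pools were hybridised together on 2 two-colour arrays with the dyes exchanged. The arrays repeat 1 measurement of the same 2 pools. They therefore count as 1 replicate: each ± below is the SD between the 2 arrays (n = 2 arrays, technical), no spread between mice was measured, and no p-value is given.

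Each array carried 41534 gene spots. On array 1 the arch RNA (Cy3) was well above background at 82.1% of them and the thoracic RNA (Cy5) at 76.5%, and on array 2 the arch RNA (Cy5) at 78.0% and the thoracic RNA (Cy3) at 82.6%. Median signals lay between 132.4 and 142.2, against means of 77.0 to 97.1 for the negative control spots, so the number of arrays and the small distance of dim probes from background limit the precision. In all, 22811 genes could be compared. Their log2 ratios of arch over thoracic had a Pearson correlation of 0.81 and a Spearman correlation of 0.58 between the arrays, taken across genes, which are not independent replicates. The SD between arrays had a median of 0.06 over genes and a 95th percentile of 0.18.

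Among the largest differences were genes of macrophages, heart muscle and body position and major urinary protein genes. Cd5l, a protein secreted by macrophages, was 17.0-fold higher in the arch pool (log2 ratio 4.09 ± 0.13), and Myl7, the atrial myosin regulatory light chain, was 12.5-fold higher (3.65 ± 0.12). Hoxa7 and Hoxb7, transcription factors of anterior-posterior patterning, were 10.9-fold and 9.21-fold higher in the thoracic pool (-3.45 ± 0.13 and -3.20 ± 0.06). By the size rule, a mean difference of at least 2-fold with at least 1.5-fold in the same direction on each array, 108 genes were higher in the arch pool and 33 in the thoracic pool. The same rule applied to the dyes instead of the segments, which counts dye bias and noise, was passed by 0 genes. In the deposited ratios, which compress dim probes less, 232 and 77 genes passed, and 14 passed for the dyes. In the main values, whose offset narrows the ratios of dim probes, 98.1% of the genes compared differed by less than 1.5-fold. True 2-fold changes in the simulated arrays came back as 1.52-fold in the median, so that share counts some larger differences as small.

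**Figure D1:**
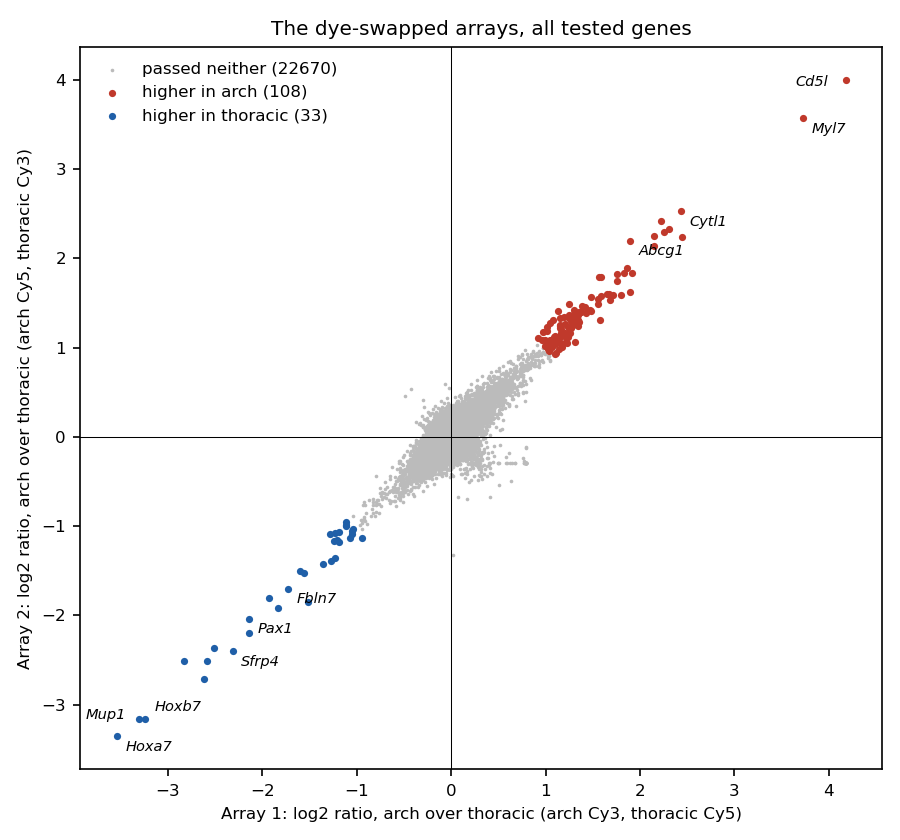
Log2 ratio of arch over thoracic on array 1 (horizontal axis) and array 2 (vertical axis) for the 22811 genes compared, each dot 1 gene. The 108 genes higher in arch (red) and the 33 higher in thoracic (blue) lie along the diagonal, from Cd5l at 4.09 to Hoxa7 at -3.45 in the mean of both arrays.

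Some macrophage, cholesterol export and matrix protease genes were higher in the arch pool, while most members of their lists passed neither way. Of 23 macrophage genes compared, 5 passed and were higher in the arch, among them Gpnmb, a glycoprotein of lysosome-rich macrophages (2.34 ± 0.14), the lectins Lgals3 (1.65 ± 0.09) and Clec7a (1.52 ± 0.05), and Mpeg1, a pore-forming protein of macrophages (1.33 ± 0.05, with a further probe at 0.36). The list's median was 0.18, at percentile 99.96 of random lists of like brightness (0.08 without loess), and 18 members passed in neither direction. All 23 were also well above background in the thoracic pool, but 21786 of the 22811 genes compared had a probe so in both pools. In the list of lipid handling genes the cholesterol exporters Abcg1 (2.05 ± 0.21) and Abca1 (1.29 ± 0.06) passed, 28 of 30 members passed neither way, and Lpl, lipoprotein lipase, stood at 0.95 ± 0.13 and Lrp1, a lipoprotein receptor, at 0.83 ± 0.03. That list's median was 0.07 (percentile 99.0), and it stood apart no longer when array 1 was left out (0.07, percentile 96.3) or when the median over each gene's probes was taken (0.03, percentile 87.4). Of 26 matrix proteases and inhibitors, Mmp12, the macrophage elastase (1.52 ± 0.06), and Ctss, the lysosomal protease cathepsin S (1.18 ± 0.09), passed, while Timp3 (0.99 ± 0.00) and Ctsb (0.96 ± 0.03, with a further probe at 0.32) lay just under 2-fold. The median was 0.24 (percentile 100.0), and 0.36 in the deposited ratios.

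Markers of mesothelium, the cell layer that lines body cavities such as the heart sac, had the largest list median with dim probes filtered out. Of 13 mesothelial and epithelial genes compared, 7 were higher in the arch pool and none in the thoracic pool, with a median of 1.16 (percentile 100.0). Without that filter the median was 0.15, under that of the interferon list, which was at least 0.35 in every setting. The surface protein Upk3b stood at 1.79 ± 0.04, the membrane protein Lrrn4 at 1.64 ± 0.05, mesothelin (Msln) at 1.44 ± 0.05 and Wt1, a transcription factor of mesothelium and epicardium, at 1.42 ± 0.06. In the thoracic pool 12 of the 13 were also well above background, as were most genes compared. Gpm6a, a membrane glycoprotein outside the lists, was 3.56-fold higher in the arch (1.83 ± 0.00), with a further probe at 0.69. Also outside them, Atp1b1, a sodium pump subunit, was 4.42-fold higher (2.14 ± 0.01) and the ubiquitin ligase Lnx1 3.67-fold (1.87 ± 0.06, its probes ranging from 0.84 to 1.87).

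Heart muscle genes were split. Of 24 compared, 6 were higher in the arch pool: besides Myl7, the cardiac troponins Tnnt2 (2.32 ± 0.13) and Tnni3 (1.41 ± 0.03) and sarcolipin, Sln (2.20 ± 0.07, with a further probe at -0.01), were among them, and the other 18 passed neither way. The median was 0.25 (percentile 100.0, and 0.54 in the deposited ratios). In the thoracic pool 22 of the 24 were well above background, as were most genes compared. Of 19 skeletal muscle genes 1 passed, the perinatal myosin heavy chain Myh8 (1.32 ± 0.05, with a further probe at -0.02), whereas Mybpc2 stood at -0.67 ± 0.08, Myl1 at 0.73 ± 0.14 and Myh4 at 0.70 ± 0.02. The median of that list, -0.10, lay lower than in nearly all random lists (percentile 0.0), but its mean had the opposite sign (0.04). Without an offset the median was -0.20.

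Endothelial genes, whose cells the detergent was meant to remove, had a median of 0.25 over 20 genes (percentile 100.0, and 0.43 in the deposited ratios). Of these, 19 lay above 0 and 1 was lower in the arch by at least 0.5 log2. Kdr, a receptor for vascular endothelial growth factor, passed (1.24 ± 0.04). Vwf, von Willebrand factor, stood at 0.87 ± 0.04, Emcn at 0.78 ± 0.03 and Ptprb at 0.71 ± 0.11. Adventitial fibroblast genes had a median of 0.24 over 18 genes (percentile 99.97), with Lama2 at 0.84 ± 0.06, Pdgfra at 0.84 ± 0.00 (a further probe at 0.12) and Abca8a at 0.81 ± 0.00. Of the 18, 14 lay above 0. Against that direction Fbln7, a secreted fibulin, was 3.28-fold higher in the thoracic pool (-1.71 ± 0.02). All members of both lists were also well above background in the thoracic pool, as were most genes compared. Brown fat genes had a median of 0.11 over 14 genes (percentile 98.5; 0.17 without an offset). Dio2, which activates thyroid hormone, passed (1.12 ± 0.03), and Cox7a1 (0.80 ± 0.04), Cox8b (0.61 ± 0.02) and Cidea (0.54 ± 0.03) did not. Without background subtraction (0.09, percentile 96.9), or without array 1 (0.11, percentile 96.5), the brown fat list did not stand apart.

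The marker lists of adipocytes, lymphocytes, nerve, pigment, thyroid and red blood cells did not stand apart. The median was 0.01 for 20 adipocyte genes (percentile 61.2, mean -0.02), in which Retn stood at -0.47 ± 0.15, Pck1 at 0.37 ± 0.01, Cfd at -0.35 ± 0.14 and Pnpla2 at 0.22 ± 0.18. Of 22 lymphocyte and thymus genes (0.02, percentile 85.0) only the interleukin receptor gene Il7r passed (1.12 ± 0.15, with a further probe at 0.16). The 21 Schwann cell and neuron genes (0.01, percentile 74.9) included Mbp at 0.55 ± 0.01 (its lowest probe at -0.01) and Uchl1 at 0.48 ± 0.01. In the other direction, Gap43 stood at -0.38 ± 0.06 and S100b at -0.35 ± 0.11. The 8 melanocyte genes had a median of -0.03 (percentile 24.6), with Mlana at -0.62 ± 0.16. The 9 thyroid and parathyroid genes had a median of -0.04 (percentile 11.5). The 6 erythroid genes had a median of 0.04 (percentile 74.6, mean -0.04). In that list the globins Hbb-bt (0.25 ± 0.77) and Hba-a1 (0.17 ± 0.66) came from saturated probes, and Alas2 stood at -0.54 ± 0.06. With saturated probes left out the erythroid median was -0.22 (percentile 0.14). Without array 1 it was -0.28 (percentile 0.02), but that value keeps the saturated globins and is not to be relied on.

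Some cartilage and matrix genes were higher in the arch pool beside these marker lists, while most members passed neither way. Of 21 cartilage and bone genes 4 passed, all higher in the arch, and the median was 0.13 (percentile 100.0), with 0.04 unfiltered and 0.28 in the deposited ratios. They were Cytl1, a secreted protein of cartilage, 5.58-fold higher (2.48 ± 0.06); Epyc, a small cartilage proteoglycan, 4.99-fold higher (2.32 ± 0.01, with a further probe at 2.52); Alpl, tissue-nonspecific alkaline phosphatase (1.19 ± 0.03); and Sox9, a transcription factor of chondrocytes (1.06 ± 0.03, with a further probe at 0.02). Of 26 proteoglycans and matricellular proteins 4 were higher in the arch, led by Spp1, osteopontin, at 4.84-fold (2.27 ± 0.02), with Cthrc1 (1.27 ± 0.19, a further probe at -0.22) and Tnfrsf11b, osteoprotegerin (1.23 ± 0.02). Tnc, tenascin C, was higher in the thoracic pool (-1.19 ± 0.14, a further probe at -0.08). The median was 0.23 (percentile 100.0). Of 31 elastic fibre and collagen genes 28 lay above 0, with a median of 0.33 (percentile 100.0). Efemp1, a fibulin, passed (1.31 ± 0.03), as did Ltbp2 (1.26 ± 0.03, a further probe at 0.06), while Fbln5 (0.81 ± 0.14, a further probe at 0.21) and Fbln2 (0.78 ± 0.06) did not.

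Immune signalling genes shifted as lists more than as single genes. None of 29 interferon response genes passed, yet 27 lay above 0 and the median was 0.39 (percentile 100.0). The highest values were those of Oasl2 (0.86 ± 0.09), Cxcl9 (0.74 ± 0.08), Ifi44 (0.68 ± 0.04) and Ifit1 (0.65 ± 0.02), of which Cxcl9 and Ifi44 passed without an offset and in the deposited ratios (up to 1.51 and 1.62). Of 15 complement genes, C3 passed at 2.14-fold (a further probe at 0.23), C4b stood at 0.55 ± 0.14 and the median was 0.19 (percentile 99.9). None of 31 chemokine, cytokine and adhesion genes passed (median 0.09, percentile 99.8). The adhesion molecule Vcam1 stood at 0.97 ± 0.08 (a further probe at 0.54), Cx3cl1 at 0.58 ± 0.02 and Ccl11 at -0.52 ± 0.06. Without loess (0.04, percentile 97.0) or without array 1 (0.07, percentile 96.0) that list did not stand apart. The 14 antigen presentation genes had a median of 0.11 (percentile 97.53), just past the limit, which 11 of the 14 alternative settings did not reach. H2-D1 stood at 0.36 ± 0.03, Cd74 at 0.34 ± 0.05, H2-K1 at 0.30 ± 0.09 and Tap2 at 0.29 ± 0.13.

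Several positional transcription factors were higher in the thoracic pool. Of 16 Hox genes of paralog groups 6 to 13, 3 passed, Hoxa7, Hoxb7 and Hoxc6 (3.64-fold, -1.87 ± 0.08), while Hoxc9, whose arch signal was not well above background, was at least 1.79-fold higher in the thoracic pool by its bound. Hoxc9 passed without an offset and in the deposited ratios (to -2.92). The median of -0.10 lay below nearly all random lists (percentile 0.02). It ranged from -0.33, with the median over each gene's probes, to -0.05, with dim probes kept. Of 13 Hox genes of groups 1 to 5, Hoxb5 passed (-1.33 ± 0.08), Hoxa5 stood at -0.68 ± 0.08 and Hoxa2 at 0.53 ± 0.10, and the list did not stand apart (median -0.04, percentile 16.3). Pax1, a transcription factor of the axial skeleton, was 4.25-fold higher in the thoracic pool (-2.09 ± 0.07). Also higher were Sfrp4, a secreted Wnt modulator, at 5.13-fold (-2.36 ± 0.06), C1qtnf3 at 4.49-fold (-2.17 ± 0.04), Esm1, endocan, at 3.67-fold (-1.88 ± 0.06) and Fhl2 at 2.92-fold (-1.55 ± 0.07). The major urinary protein genes Mup1 (9.39-fold, -3.23 ± 0.10, its probes ranging from -3.23 to -1.05) and Mup4 (5.41-fold, -2.44 ± 0.10) belong to a family of near-identical copies, so which copy gave the signal is uncertain.

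**Figure D2:**
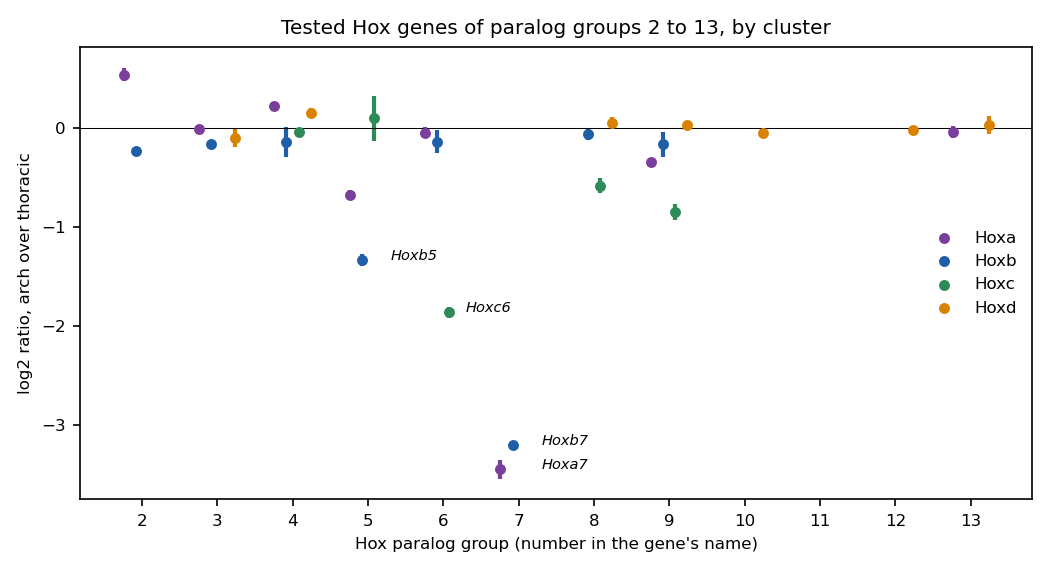
Log2 ratio of arch over thoracic (vertical axis) for the Hox genes compared in paralog groups 2 to 13, by group (horizontal axis) and cluster (colour); dots are means of both arrays and bars span the 2 arrays. Hoxa7 (-3.45), Hoxb7 (-3.20), Hoxc6 (-1.87) and Hoxb5 (-1.33) are the 4 that passed the size rule. The dot of Hoxc9, whose arch signal was not well above background, understates a difference known only as a bound.

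Smooth muscle genes themselves differed little. None of 23 contractile smooth muscle genes passed. Their median of 0.15 (percentile 99.7) turned to -0.02 without loess. Of them 3, Acta2, Tagln and Myl9, sat on saturated probes, whose ratios are set by the scanner's ceiling, so their difference was not measured. Csrp1 stood at 0.39 ± 0.16, Itga8 at -0.37 ± 0.08, Actg2 at 0.29 ± 0.03 and Cald1 at 0.28 ± 0.16. Of 36 vasoactive receptor and cyclic nucleotide genes (0.01, percentile 75.5, mean -0.01) the vasopressin receptor Avpr1a (-1.05 ± 0.00, and -0.82 without background subtraction) and Rgs2, which dampens G-protein signalling (-1.04 ± 0.13, a further probe at -0.37, and -0.95 without array 2), were higher in the thoracic pool. In the same list Rgs5 stood at -0.70 ± 0.06 and Npr3 at 0.68 ± 0.01. None of 26 calcium handling and ion channel genes passed (0.04, percentile 93.8), with Abcc9 at 0.64 ± 0.03 and Itpr3 at 0.62 ± 0.06. None of 25 outflow tract and neural crest transcription factors passed either. Their median of 0.09 lay high (percentile 99.8), but their mean was -0.01, with Tbx1 at -0.66 ± 0.13, Snai2 at -0.66 ± 0.08 and Isl1 at 0.53 ± 0.06, and without array 1 the median was 0.05 (percentile 91.4).

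Among signalling and housekeeping lists, none of 32 TGF-beta and BMP genes passed (median 0.16, percentile 100.0), with Fst at 0.68 ± 0.00. Gdf6, whose thoracic signal was not well above background, was at least 1.46-fold higher in the arch by its bound, and passed without an offset and in the deposited ratios (up to 2.65). None of 26 redox genes passed (0.15, percentile 99.9), with Gpx3 at 0.67 ± 0.17. Of 31 Wnt genes (0.03, percentile 92.3) Frzb, a secreted Wnt antagonist, was higher in the arch (1.03 ± 0.12, and 0.94 without array 1 or background subtraction, under the limit) and Sfrp4 in the thoracic pool. The lists of Notch signalling (14 genes, 0.03, percentile 87.4), immediate early and stress genes (25 genes, 0.07, percentile 92.1), proliferation (22 genes, 0.03, percentile 84.3), oxidative phosphorylation (34 genes, -0.03, percentile 17.1), ribosomal proteins (35 genes, median -0.01 and mean 0.00, percentile 35.2) and the circadian clock (17 genes, 0.00, percentile 55.0) did not stand apart and had no member past the size rule. In these, Hey1 stood at 0.63 ± 0.08, Egr2 at 0.78 ± 0.02, Mki67 at 0.27 ± 0.09 and Rrm2 at -0.36 ± 0.08. Of the 35 ribosomal protein genes 11 sat on saturated probes, so their difference was not measured. Of the 38 lists with at least 5 genes compared, 19 stood apart towards the arch and 2 towards the thoracic pool. Of lists of genes drawn at random, about 5 in 100 do so. Genes of 1 list can vary together, so that rate is only a loose yardstick.

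**Figure D3:**
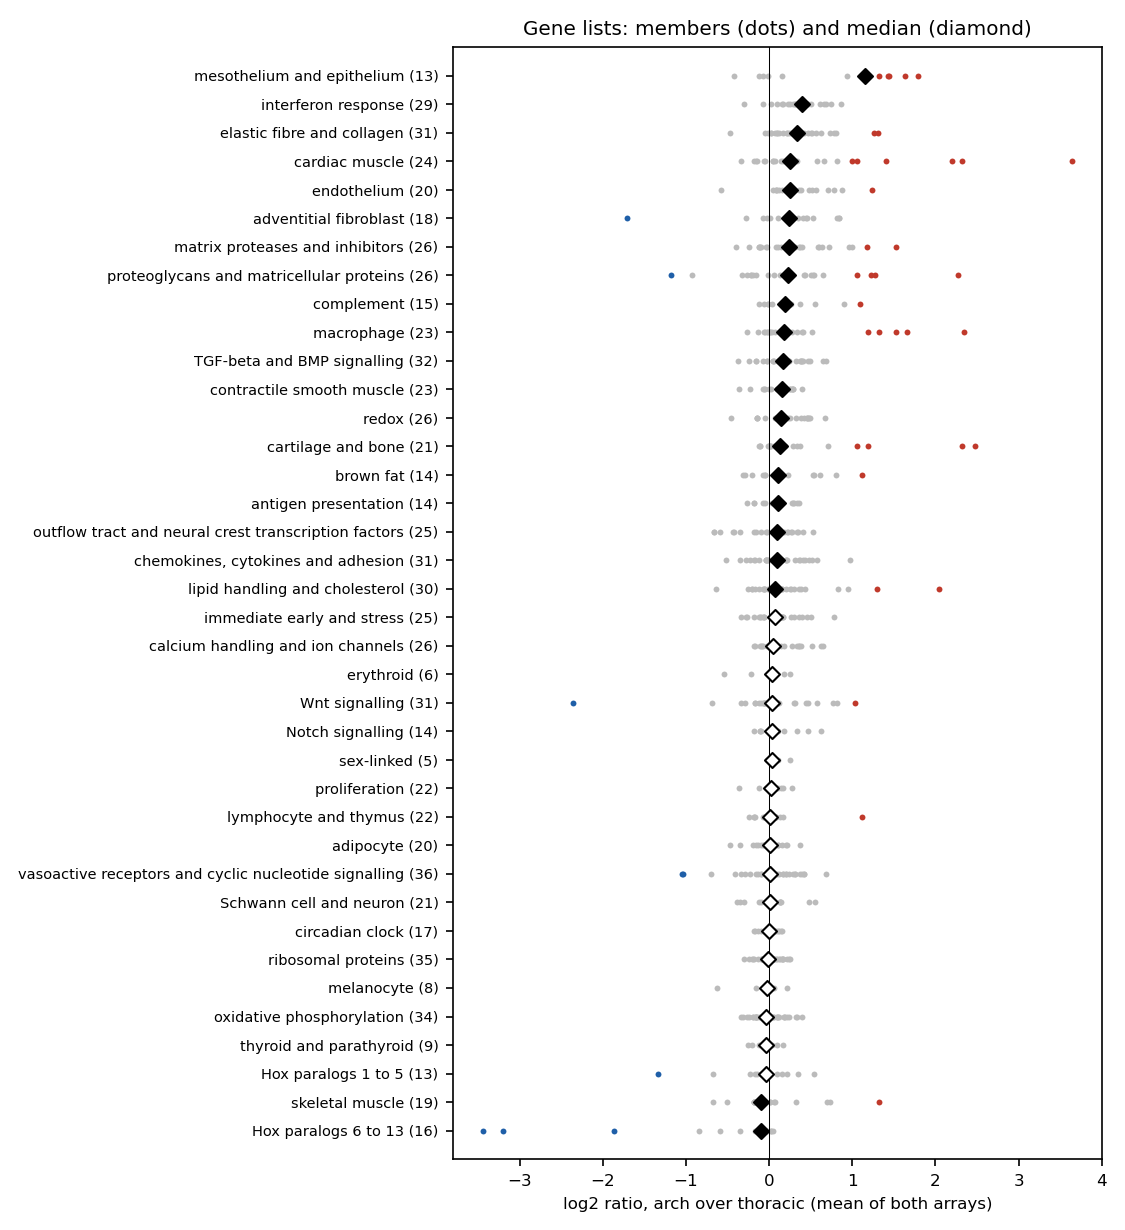
Log2 ratio of arch over thoracic (horizontal axis) for the members of the 38 gene lists (dots; red higher in arch, blue higher in thoracic, grey neither) and each list's median (diamond; filled where it stood apart from random lists). The number in brackets counts the genes compared; medians run from 1.16 for mesothelium and epithelium to -0.10 for the Hox genes of groups 6 to 13.

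Apoe, the gene knocked out in these mice, gave a ratio of 0.13 ± 0.14 with signal in both pools. Whether its probe lies in the deleted part is not given in the sources used here, so the value checks neither label. The 5 sex-linked genes (median 0.03, percentile 69.9) lay between -0.03 (Eif2s3y) and 0.25 ± 0.10 (Ddx3y), with Kdm5d at 0.11, Xist at 0.03 and Uty at 0.01, in pools that held both sexes in equal number.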

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

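Among the positive control probes, which enter no comparison, 2 types were at least 2 times as bright as the negative control spots in both dyes on both arrays, at lowest ratios of 2.41 and 2.36 times. The other 55 of 57 types were not, and 40 of these were bright in green alone on both arrays. As the dyes were exchanged between the arrays, that brightness followed the dye and not the pool. No further explanation was tested.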

How the results depend on the processing

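Of the 51 named genes that passed the size rule, 39 passed under every alternative that gave a value, and none of the 51 changed direction. Calls were lost with the median over probes by C3, Cthrc1, Il7r, Ltbp2, Mpeg1, Myh8, Rgs2, Sox9 and Tnc, without background subtraction by Avpr1a, Frzb, Il7r and Sox9, without loess by C3 and Ctss, without array 1 by Frzb and without array 2 by Rgs2. Of the 114 that did not pass, 99 passed under no alternative. Without an offset and in the deposited ratios and the series table Cxcl5, Cxcl9, Gdf6, Hoxc9, Ifi44, Isl1, Mybpc2, Myh4, Npr3, Vcam1 and Vwf passed, in the deposited ratios and the series table also Gap43, Hoxa5 and Ptprb, and without array 2 Lpl and Vcam1. Of the 21 lists that stood apart, 15 did so under every alternative. Of the 17 that did not, 13 did so under none. The cause of a change was not tested unless stated.

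Against 108 genes higher in arch and 33 higher in thoracic, normexp without an offset gave 196 and 66, with 7 passing for the dyes. The deposited log ratio gave 232 and 77, with 14 for the dyes, and the values of the series table gave the same 232 and 77, with 14. The offset of the main values narrows the ratios of dim probes by construction. All 108 and all 33 genes were among those called from the deposited ratios. A 1.5-fold limit gave 274 and 87, and a 3-fold limit 23 and 14, by construction. With 1 array, 103 to 114 genes were higher in arch and 33 in thoracic. The share of calls higher in arch, 76.6%, was 62.2% at 3-fold. The correlation between arrays, 0.81, was 0.75 with no filter on dim probes, 0.63 in the deposited ratios and 0.32 without loess (Spearman -0.08), where dye trends with brightness remain.

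Without loess the contractile smooth muscle list turned to -0.0242 and the chemokine list stood at 0.0366. The antigen presentation list lost its standing with no background subtraction (0.0910), without an offset (0.0999), in the deposited ratios and the series table (0.103 in both), without loess (0.0375), with the filter on both RNAs (0.107), the median over probes (0.0684), outlier spots kept (0.107), saturated probes left out (0.107), without array 1 (0.0275) and without array 2 (0.0779). The lipid list lost it with the median over probes (0.0290), and the brown fat list with no background subtraction (0.0855). The erythroid list turned to -0.222 without saturated probes. Immediate early genes (0.0668) stood apart at percentile 99.2 against unmatched lists.

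Leaving out array 1 ended the standing of outflow tract factors (0.0538, with 0.0962 without array 2), chemokines (0.0660, with 0.101), lipid handling (0.0687, with 0.0876) and brown fat (0.105, with 0.110). It turned the erythroid list to -0.282 (-0.0667 without array 2) and made immediate early genes (0.112, with 0.0692) and ribosomal proteins (-0.105, with -0.0072) stand apart. Of the 35 ribosomal protein genes 11 sat on saturated probes, whose ratios are set by the scanner's ceiling, as did 2 of the 6 erythroid genes. The values of these lists on 1 array are therefore not to be relied on. Leaving out array 2 made Notch genes stand apart (0.0929, with 0.0304).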

Other observations

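Outside the lists, some genes were chosen after their values were seen, so that they test nothing. Bnc1 (1.16 ± 0.16), Muc16 (1.38 ± 0.02) and Aldh1a2 (1.07 ± 0.01), which mesothelial cells express, were higher in the arch pool, as was Tcf21 (1.76 ± 0.19), a transcription factor of epicardial cells and their descendants. Atp6v0d2, a proton pump subunit of lysosomes, at 2.99-fold and the lipid-binding protein Fabp5 (1.11 ± 0.10) were higher there too, beside the macrophage genes. Myoglobin, Mb (1.27 ± 0.10), was also higher in the arch. In the thoracic pool Calcrl, the calcitonin receptor-like receptor (-1.29 ± 0.09, with a further probe at -0.09) and the acute-phase gene Saa3 (-1.05 ± 0.08) were higher.

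The hypotheses below were found in these pools. Each was set against a further marker list, written with its limits before that list's genes were looked at. Genes already seen to differ were therefore left out of these lists, 0 of their members passed, and a low median in them excludes nothing. The 3 lists of general macrophage, mesothelial and heart muscle genes met the limits written for a rejection, which for that reason rejects nothing. The test on the macrophage list fixed at first was chosen only after its values were seen. The region itself, which the design compares, stays open as the biological explanation of each pattern and was not tested, since there is 1 pool per segment.

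Higher macrophage genes in the arch may come from a larger share of the same macrophages, which would raise about alike those that no other cell expresses. The list fixed at first, with its called genes, had a median of 0.18 over all 23 members (95% bootstrap interval over genes, 0.01 to 0.41), below the rise of at least 2-fold that its 5 passing members need. The members were thus not raised alike in these values. With 18 of the 23 already seen not to pass, a median under that rise was fixed beforehand, so it decides nothing about the share. The further list of 22 general macrophage genes had a median of 0.10 (-0.02 to 0.22, percentile 99.0, and 0.11 in the deposited ratios). The limits were at least 0.5 for a larger share, and under 0.3 with an interval ending below 0.5 against it. The latter were met, but by a list without the genes already seen to differ. A larger share stays open. Macrophages in another state, with lipid and lysosome gene expression, are a candidate explanation. The 22 genes of the lipid and lysosome list had a median of 0.19 (0.06 to 0.35; percentile 100; 0.19 in the deposited ratios), between the limits of 0.1 and 0.3, so the list does not decide it. Its members ranged from Ctsd at 0.99 to Itgax at -0.17.

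Higher mesothelial genes in the arch may come from more mesothelium, such as that of the heart sac, left on the arch segment. The further list of 15 genes had a median of 0.10 (0.03 to 0.36, percentile 99.3), and 0.20 in the deposited ratios. The limits were at least 0.5 for the explanation, and under 0.2 with an interval ending below 0.5 against it. The main values met the latter, but in a list without the genes already seen to differ. Of the 15, 6 lay within 2 times the negative controls in both pools. The list does not decide it.

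Higher heart muscle genes in the arch may come from muscle of the heart carried along with the aortic root. The further list of 20 genes had a median of 0.0419 (-0.02 to 0.19, percentile 97.7), and 0.13 in the deposited ratios, against the same limits. Those against the explanation were met, but by a list without the genes already seen to differ. Of the 20 genes, 12 lay within 2 times the negative controls in both pools. In the list fixed at first, 18 of 24 members lay above 0 and 6 passed. Neither list decides it.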
